A study of Oryza sativa with 6 samples.

How the data were processed

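RNA from leaves of 3 wild type and 3 OsCGA1-overexpressing rice plants was labelled with biotin from 5 µg of total RNA and hybridized to Affymetrix Rice Genome Arrays, per the labels' protocols. The deposited values are linear probe set intensities made with MAS5, per the submitters' processing notes, with no version given in the sources used here. After trimming 2% at each end, the mean of every array was 100, so the values were taken as already scaled between arrays. The scaling target, detection calls and scanner files were not used here, so probe sets not above background could not be marked. The sizes of fold changes of dim genes are therefore uncertain. Median signals per array were 16.8, 18.2 and 18.7 in wild type and 14.7, 16.2 and 15.8 in overexpression. The number of arrays limits the precision.

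The table held 57381 probe sets, of which 187 controls (names starting AFFX or RPTR) were kept out of the fit. The probe annotation gave 22436 probe sets 1 gene symbol and 95 several, and 34663 non-control probe sets none. No gene was named from a probe set with several symbols. The 17905 genes with a probe set of their own all matched the RefSeq gene table (assembly ASM3414082v1) by Entrez ID, which was used for names alone. Of these, 2457 had a name other than a locus or clone ID. Synonyms can follow several numberings: MT2B (LOC4326409) and MT2C (LOC4337596) each carry the other's name, PHT1-2 (LOC4335115) also PHT1-4, OPR10 (LOC4340486) also OPR4 and ORR4 (LOC4328516) also RR24. No gene in these tables is called OsCGA1, so the planned check of that gene was not run and nothing else here checks the label.

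Signals were analysed as log2(signal + 3), where 3 is the 20th percentile of all non-control values, rounded. Probe sets with a mean over the 6 arrays of at least 16.8, the median of all non-control values, were tested, which left 28456. Folds are on this log2(signal + 3) scale, which understates changes of low signals. limma 3.58.1 in R 4.3.3 was fitted with genotype alone (lmFit, eBayes with a variance trend, two-sided) and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 counted as passed. In simulated data for this comparison with 200 of 28456 probe sets changed, the fit called 6% of those changed by 0.5 on the log2 scale, 50% at 1, 84% at 2 and 94% at 3, with 13 calls among 28256 unchanged probe sets. Thus 10% of its 130 calls were false, above the nominal 5%, in a single simulated draw. The cutoff of the adjustment depends on how many probe sets change, and the real comparison gave 4578 calls. These rates therefore do not carry over to it. A simulated list of 20 genes shifted by 1 was called, and 0 of 30 unchanged lists were. Members of the simulated lists varied independently, while the estimated correlation in the real ribosomal list was 0.548. The simulation therefore gives no rate of false calls for correlated lists.

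Gene lists were tested with 1 probe set per gene, that with the highest mean signal among those tested. Counts used the adjusted p over all probe sets, and, for planned lists, also an adjustment over the list alone. Lists with at least 5 tested genes were compared with all other genes by camera (preset correlation 0.01, and again with an estimated correlation) and tested by fry, with Benjamini-Hochberg adjustment over 33 lists. List themes, tests, filter, pseudocount and the rule for named genes were fixed before the data were examined. That held for 22 of the 39 lists with tested members. The planned lists had been written as locus IDs and descriptions, which the tables lack, so members were resolved through symbols and synonyms after the annotation was seen. Some members outside the planned wording entered only then, after array summaries but before any gene-level comparison. They include D35, KAO, EUI1, SLR1 and CPS1 of the gibberellin list, OEP80, the ROC genes and TRAB1. For roots, also a planned theme, all 6 tested genes entered then (Lsi1, YSL15, IRT1, IRT2, NRAMP5 and HKT1;5), so that list is not counted as planned. The other 17 lists (roots, plastid proteases, plastid isoprenoids, expansins, sugars, auxin, aquaporins, peroxide removal, phosphate, metals, ethylene, brassinosteroid, phenylpropanoids, metallothioneins, seed storage, meiosis and photoreceptors) were also written at that point. Plastid division and plastid ribosomal protein genes were planned and not analysed here.

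Genes named in the text were GLK1 and GLK2, the 10 highest and 10 lowest log2 changes among named genes that passed with non-overlapping groups (1 probe set per gene), and up to 4 members of each list with the smallest p. After the annotation was seen, at most 2 rising and 2 falling genes known by ID alone were added. All pairs of 3' and 5' control probe sets, 42 in number, were used for signal ratios. Control probe sets were compared by exact permutation tests, whose smallest possible p is 0.1 for 3 arrays against 3. No pair of arrays held the same values throughout. The alternatives were no pseudocount, 4 times the pseudocount, no filter and a stricter filter, quantile normalization, centring on the median, no variance trend, array weights, the replicate number as a block, leaving out each array, other thresholds, leaving out probe sets that may bind several transcripts, and other units for genes and lists.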

Results

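The series measured RNA in leaves of 4-week-old rice (Oryza sativa) with a 1-colour Affymetrix Rice Genome Array. It compared wild type plants with plants overexpressing OsCGA1, a GATA-type transcription factor, with 3 biological replicates of each. The series title names chloroplast development as the subject, so the comparison addresses which leaf transcripts differ when this factor is overexpressed. All plants were grown under 16 h of light at 28 °C and 8 h of darkness at 23 °C. Median signals per array lay between 14.7 and 18.7. Across tested probe sets, arrays correlated at 0.967 to 0.969 within wild type, 0.9465 to 0.9675 within overexpression and 0.911 to 0.926 between the genotypes. The number of arrays limits the precision. Values after ± are standard errors of the log2 change (overexpression minus wild type, n = 3 arrays per genotype), unless SD is named. "Rose" and "fell" are used only for probe sets with an adjusted p under 0.05 from limma.

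Overexpressing leaves had far more transcript of the aquaporin OsPIP2;6, a plasma membrane water channel, and of EIL1B, an EIN3-like factor of the ethylene pathway. The OsPIP2;6 signal was 8.93 ± 12 (SD, n = 3) in wild type and 1059 ± 220 (SD, n = 3) in overexpression. EIL1B (LOC4332697) went from 383.7 ± 29.1 to 3582 ± 101 (SD, n = 3 each), a 9.28-fold rise with an adjusted p of 5.19e-06 from limma. At the other end, OsPP2C12, a type 2C protein phosphatase, fell from 847.2 ± 110 to 75.8 ± 23.4 (SD, n = 3 each). The late embryogenesis protein gene EM fell by 3.07 ± 0.60 on the log2 scale, while another gene of that class, LEA19, rose by 3.15 ± 0.88. LEA19 did not pass in 8 of 15 alternative settings, and EM in 2 of 15.

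The other named genes with the largest rises were BURP16 (3.83 ± 0.47), ABA8OX1 (3.80 ± 0.73), LAC19 (3.68 ± 0.39), CYP71Z7 (3.31 ± 0.47), DREB1G (3.16 ± 0.89) and EL2 (3.15 ± 0.35). ABA8OX1 encodes an abscisic acid 8'-hydroxylase, LAC19 a laccase and DREB1G a member of the DREB1 factor family. DREB1G did not pass in 8 of 14 alternatives, and ABA8OX1 in 1 of 14. The wild type signals of LAC19 (1.03), BURP16 (3.8), EL2 (3.8), ABA8OX1 (6.73) and DREB1G (8.3) lay near the pseudocount of 3, so the size and order of their rises depend on it. With 4 times the pseudocount and with none, LAC19 was at 2.22 and 5.47, EL2 at 2.13 and 3.95 and ABA8OX1 at 2.83 and 4.61. A probe set of LOC4348646 rose by 3.23 ± 0.17, but that gene carries the names HSFA2C and ARD1 among its synonyms and its second probe set was at 0.29 with an adjusted p of 0.296. The other named genes with the largest falls were PM1 (-2.76 ± 0.67), URH2 (-2.20 ± 0.49), CYP714C2 (-1.88 ± 0.37), HSP17.7 (-1.76 ± 0.18) and D35 (-1.65 ± 0.15). The nicotianamine synthase genes NAS1 and NAS2, which serve iron transport, fell, with log2 changes of -1.87 ± 0.36 and -1.65 ± 0.30. PM1 did not pass in 6 of 15 alternatives and URH2 in 4 of 14. A probe set of the metallothionein gene MT2B fell by 2.21 ± 0.29, while its other probe sets were at 0.12 and 0.14 and did not pass. Among genes known here by ID alone, LOC4343954 and LOC4344104 rose by 6.21 and 5.79, and LOC4351341 and LOC4328793 had changes of -6.25 and -5.90. The other tested probe sets of LOC4344104 and LOC4351341 did not pass (-0.18 and -0.45), and those of LOC4343954 ranged from -0.44 to 5.91. LOC4343954 read 0.3 to 1.8 on the wild type arrays, below the pseudocount, so the size of its rise is set by it (4.51 with 4 times the pseudocount and 7.86 with none).

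**Figure D1:**
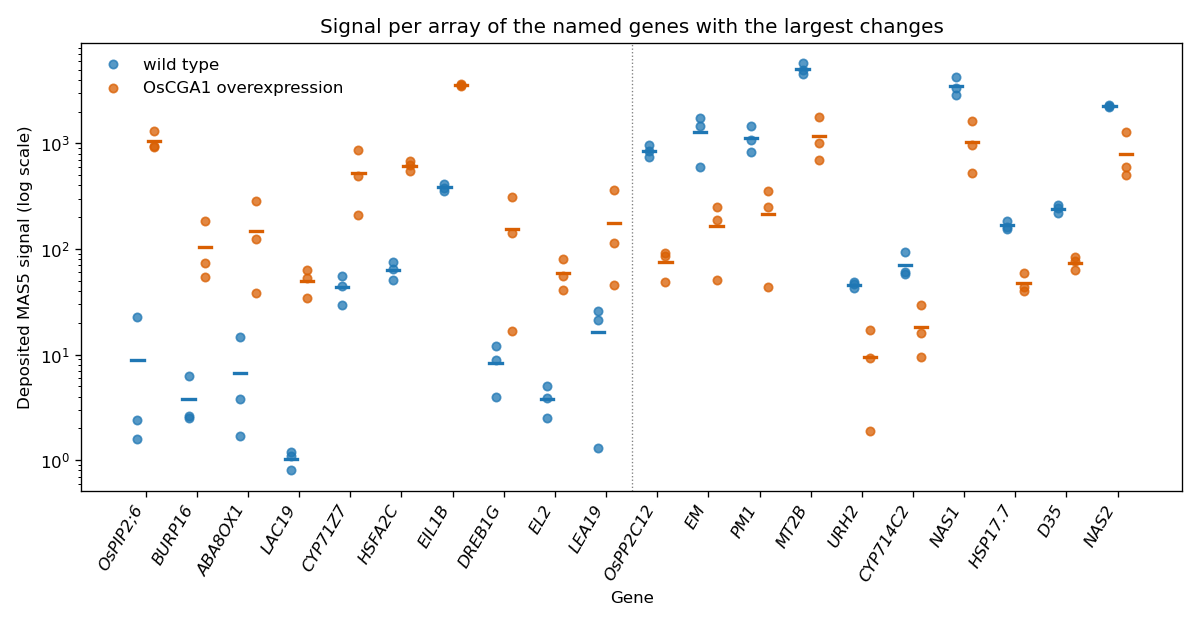
Deposited signal of each array (points, logarithmic axis) and mean of 3 arrays (bars) for the 10 named genes with the largest rises (left of the dotted line) and the 10 with the largest falls, in wild type (blue) and overexpression (orange). The gene drawn as HSFA2C is LOC4348646. EIL1B lies near 383.7 in wild type and near 3582 in overexpression. Genes were chosen among those whose arrays do not overlap between the genotypes.

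Of 28456 probe sets tested, 4578 passed, 2461 higher and 2117 lower in overexpression. The majority turned without overexpression replicate 2 (2631 higher and 2902 lower), with array weights and at an adjusted p under 0.10, and the share of higher ones ran from 46.7% to 65.6% over the alternatives. Of these 4578, 1670 changed at least 2-fold, 1095 up and 575 down. Counted with 1 probe set per gene, 2796 of 14616 genes passed. Among the 2069 with an informative name, 450 passed, 260 higher and 190 lower. A list count below that lies near this share marks no response particular to the list. All 4578 had non-overlapping groups, as did 38.7% of all tested probe sets, against the 10% that chance gives for 3 arrays against 3. The count was 2408, 2287 and 2483 without wild type replicates 1, 2 and 3, and 2230 without overexpression replicate 3. The 3'/5' signal ratio, a sign of RNA quality, was higher on every overexpression array than on any wild type array in 2 of the 3 actin pairs at or above the filter (for 1 of them 1.79 ± 0.24 in wild type and 2.60 ± 0.70 in overexpression, SD, n = 3 each, exact permutation p = 0.1, two-sided). The third actin pair overlapped (3.72 ± 0.775 and 4.63 ± 0.994, SD, n = 3 each, exact permutation p = 0.4), and the GAPDH ratio was lower in overexpression (4.02 against 4.74, exact permutation p = 0.2). Overexpression replicates 1, 2 and 3 had ratios of 7.29, 3.75 and 3.25 in 1 separated actin pair and 3.4, 2.16 and 2.22 in the other. Some spiked-in control pairs, which carry no leaf RNA, separated the genotypes as well. The median change over all tested probe sets was -0.09, and OsCGA1 itself was not analysed here, so the overexpression label has no check from its own target.

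Transcripts of GLK1 and GLK2, GARP factors that promote chloroplast gene expression, fell by 0.63 ± 0.13 and 0.50 ± 0.10. Both also passed adjusted over their list of 2 genes alone, which was bound to follow and adds no support. Genes for the photosynthetic apparatus mostly had slightly lower signals that did not pass, with LHCP at 0.003 under quantile normalization, and genes for chlorophyll synthesis showed no common shift. Among 16 tested genes of tetrapyrrole and chlorophyll synthesis, 1 rose and 0 fell, also when adjusted over the list alone. The riser was PPOX1, a protoporphyrinogen oxidase, at 0.39 ± 0.09, which did not pass in 7 of 15 alternatives. CHLH, a subunit of magnesium chelatase, was at -0.54 ± 0.17 and CHLP at -0.31 ± 0.13, and neither passed, except in 3 and 2 of 15 alternatives. All 3 light-harvesting genes (CAB2R at -0.31 ± 0.10, RCABP69 at -0.32 ± 0.13 and LHCP at -0.29 ± 0.12) missed the threshold over all probe sets and passed adjusted over the list alone. The same held for all 4 Calvin cycle genes, among them rca, which encodes rubisco activase (-0.32 ± 0.11). Adjustment over so few genes sets a low bar: 9406 of all 28456 tested probe sets had an unadjusted p under 0.05 from limma. Over all probe sets, CAB2R, rca and FBPase passed in 3 of 15 alternatives each. Of 9 genes of photosystems and electron transport, 1 fell (6 adjusted over the list alone, with 1 higher), namely LFNR1 at -0.68 ± 0.12. Under quantile normalization CAB2R was at -0.05, RCABP69 at -0.04 and rca at -0.01, while PSAG was at -0.38 against -0.39 without it and FBPase at -0.245 against -0.31. With that normalization LFNR1 was at -0.43 and still passed, and GLK1 and GLK2 changed by -0.62 and -0.48 and still passed. The central 95% of the medians of 10000 random lists of equally bright genes ran from -0.36 to -0.21, against -0.31 for the 16 light-harvesting, photosystem and Calvin cycle genes. GLK1 lost its call in 3 and GLK2 in 4 of 15 alternatives.

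The plastid import channel gene TOC75 rose by 0.35 ± 0.10, the only riser among 4 import and envelope genes, with the same count adjusted over the list alone. It did not pass in 9 of 15 alternatives. The plastid chaperone gene CLPD1 rose by 2.04 ± 0.30 and CLPC3 fell by 1.46 ± 0.23 among 28 genes of plastid proteases and thylakoid biogenesis, where no other member passed. Of 16 plastid isoprenoid, carotenoid and tocopherol genes, ISPE rose by 0.76 ± 0.15 and ISPG fell by 0.41 ± 0.11. Transcripts for chlorophyll breakdown included 2 risers among 5, SGR at 1.51 ± 0.29 and NYC1 at 0.85 ± 0.19, with 3 adjusted over the list alone. SGR encodes the stay-green protein and NYC1 a chlorophyll b reductase.

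The nitrate reductase gene NIA1 fell from 7458 to 2643 signal units, by 1.5 ± 0.11 on the log2 scale. The glutamine synthetase genes GLN1-1 and GLN2 fell by 0.73 ± 0.12 and 0.38 ± 0.10, and the ammonium transporter gene AMT3-2 rose by 1.86 ± 0.45. In all, 5 of 15 nitrogen genes fell and 1 rose (6 and 1 adjusted over the list alone). Among 11 starch genes 3 rose and 0 fell (4 and 0 adjusted over the list alone). DPE2, a disproportionating enzyme of maltose metabolism, rose by 1.15 ± 0.10, the starch synthase gene SSI by 1.15 ± 0.16 and the branching enzyme gene SBE by 0.53 ± 0.10. In the sucrose and sugar transport list, 5 of 31 genes rose, including OsSUT2 (0.65 ± 0.12) and SUS4 (0.77 ± 0.15), and 3 fell, including SWEET1A (-0.43 ± 0.09).

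Among 14 gibberellin genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), including D35, KAO of gibberellin synthesis (-1.40 ± 0.20), the deactivating oxidase EUI1 (-1.28 ± 0.28) and the DELLA repressor gene SLR1 (-0.48 ± 0.11). These 4 entered the list after the annotation was seen. D35 (LOC4341347) carries names of more than a single kaurene oxidase or oxidase-like gene among its synonyms, so its place in gibberellin synthesis is uncertain, and its other probe set was at -0.95 (adjusted p 0.0318). Camera, which compares a list with all other genes, gave an adjusted p of 0.0425, and adjusted p = 0.415 with an estimated correlation. The call also ended with the stricter filter (0.169), with array weights (0.0601), without wild type replicate 2 (0.0553) and without overexpression replicate 1 (0.0605). Among 26 cytokinin genes 5 fell and 1 rose (6 and 2 adjusted over the list alone). The response regulators ORR4 and RR2 fell by 0.61 ± 0.11 and 0.57 ± 0.14, LOGL7 fell by 0.66 ± 0.14 and LOGL1 rose by 0.82 ± 0.13. Of 38 auxin response genes 4 fell, including IAA2 (-1.09 ± 0.13), and 1 rose, the conjugating enzyme gene GH3-8 (2.31 ± 0.28). The auxin list had a camera adjusted p of 0.114 (lower), and passed with the stricter filter (0.0457) and without overexpression replicate 1 (0.0319). In the ethylene list of 9, ETR3 and EIN2 fell by 0.47 ± 0.12 and 0.42 ± 0.12 beside the rise of EIL1B, but did not pass in 7 and 10 of 15 alternatives. None of 9 brassinosteroid genes passed (BZR1 was at -0.40 ± 0.19), nor any of 3 strigolactone genes, also adjusted over the list alone (D14 was at -0.31 ± 0.11).

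Of 23 cytosolic ribosomal protein genes 17 rose and 0 fell (20 and 0 adjusted over the list alone). RPL5 rose by 0.95 ± 0.11, RPL3 by 0.86 ± 0.10, RPL7A-2 by 0.84 ± 0.10 and RPL9 by 0.82 ± 0.10, and the list's median was 0.52. The adjusted p from camera was 2.53e-10 at the preset correlation of 0.01 and adjusted p = 0.415 with an estimated correlation. Of 23 jasmonate and wounding genes 10 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p 0.0044, and adjusted p = 0.415 with an estimated correlation). The lipoxygenase gene CM-LOX2 rose by 2.04 ± 0.22, the repressor gene JAZ11 by 1.88 ± 0.23 and OPR10 by 1.33 ± 0.17, while LOX2 fell by 0.77 ± 0.12. In the defence list 7 of 16 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p 0.0141, and adjusted p = 0.415 with an estimated correlation). OsWRKY76 and OsWRKY62, pathogen-responsive WRKY factors, rose by 1.70 ± 0.28 and 1.68 ± 0.26, and the chitinase gene Cht2 by 1.92 ± 0.52.

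Of 6 photoreceptor genes 3 fell and 0 rose (camera adjusted p 0.0141, and adjusted p = 0.415 with an estimated correlation). The blue-light receptor gene PHOT1A fell by 1.60 ± 0.25, CRYD by 0.60 ± 0.16 and phyC by 0.38 ± 0.10. CRYD did not pass in 9 and phyC in 8 of 15 alternatives, while PHOT1A passed in all 15. Among 7 circadian clock genes, which stand for harvest time, PCL1 rose by 1.22 ± 0.22 and PRR37 and PRR95 fell by 0.81 ± 0.19 and 0.48 ± 0.14 (2 and 4 adjusted over the list alone). The clock list as a whole had a camera adjusted p of 0.533, for a shift in 1 direction. Its members moved both ways, so that value cannot exclude a difference in harvest time. For change in either direction its adjusted p from fry was 0.00509, a test that 31 of 33 lists passed. Of 34 heat shock and chaperone genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with HSFB1 at 1.62 ± 0.23 and HSP17.7 at -1.76 ± 0.18. The risers include LOC4348646, whose synonyms belong to more than a single gene. Of 17 water deficit and abscisic acid genes 2 rose and 3 fell (3 and 4 adjusted over the list alone). There ABA8OX1 rose while its relative ABA8OX2 fell by 0.96 ± 0.14.

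In the root list, whose 6 tested genes were chosen after the annotation was seen, 3 fell and 0 rose (camera adjusted p 0.0435, and adjusted p = 0.415 with an estimated correlation). The list's call also ended with no filter (0.0709), quantile normalization (0.0826), no variance trend (0.0514) and array weights (0.0601). It ended as well without wild type replicates 1 (0.0751) and 2 (0.0553) and without overexpression replicate 2 (0.0529). The silicon transporter gene Lsi1 fell by 1.39 ± 0.18, the iron carrier gene YSL15 by 1.63 ± 0.31 and IRT1 by 0.80 ± 0.23. IRT1 did not pass in 12 of 14 alternatives. Lsi1 also stands in the aquaporin list, and YSL15 and IRT1 in the metal transport list. In the secondary wall list of 12, LAC19 rose and CESA9 (-1.02 ± 0.23) and LAC10 (-1.26 ± 0.30) fell, with the same counts adjusted over the list alone. Of 9 epidermis and cuticle genes 2 fell, Roc2 at -0.54 ± 0.11 and LTPL1 at -0.45 ± 0.12 (3 adjusted over the list alone). Of 24 meristem and floral genes 3 fell, MADS26 at -1.59 ± 0.27 among them, and 1 rose, MADS57 at 2.81 ± 0.49, also adjusted over the list alone. The wild type mean of MADS57 was 3.1, and its rise was 1.66 with 4 times the pseudocount and 4.03 with none. Of 11 genes of dividing cells, H2B.10 rose by 0.93 ± 0.11 and H2B.5 fell by 0.39 ± 0.08 (2 and 2 adjusted over the list alone). None of 3 seed storage genes passed (RA14 was at -0.46 ± 0.18), and of 8 meiosis genes only SPO11-3 did, at -0.42 ± 0.09.

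Among 21 aquaporins 8 fell, including OsPIP1;1 (-0.57 ± 0.10) and Lsi1, and 3 rose, including OsPIP2;6 and OsPIP1;3 (1.03 ± 0.13), with a camera adjusted p of 0.0435 for lower values, and adjusted p = 0.415 with an estimated correlation. The median was -0.50 and the mean -0.04. Under quantile normalization the median was -0.22 and the call ended (0.165). It also ended with either other filter (0.0681 and 0.0925), no variance trend (0.0852), array weights (0.0601) and the mean over a gene's probe sets (0.103). The same held without wild type replicates 2 (0.0982) and 3 (0.0731) and without overexpression replicate 2 (0.056). Of 31 metal transport genes 7 fell and 3 rose, with YSL13 at 1.81 ± 0.15 and YSL14 at -1.37 ± 0.14. In the phosphate list of 9, the transporter gene PHT1-8 rose by 1.72 ± 0.18, and OsSPX2 and PHT1-2 fell by 1.22 ± 0.14 and 0.85 ± 0.15. Ascorbate peroxidase genes APX5 and APX7 rose by 1.26 ± 0.16 and 0.71 ± 0.14 among 13 genes of peroxide and superoxide removal, of which 3 rose and 2 fell. In the phenylpropanoid list of 14, 3 rose, including CAD6 (1.39 ± 0.21) and 4CL5 (1.39 ± 0.25), and 4CL4 fell by 0.68 ± 0.12. Of 7 metallothionein genes MT1A and MT1B rose by 0.67 ± 0.16 and 1.42 ± 0.37 and MT2C fell by 1.04 ± 0.29. Among 18 expansins EXPA10 rose by 1.04 ± 0.15 and EXLA1 fell by 0.89 ± 0.10.

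**Figure D2:**
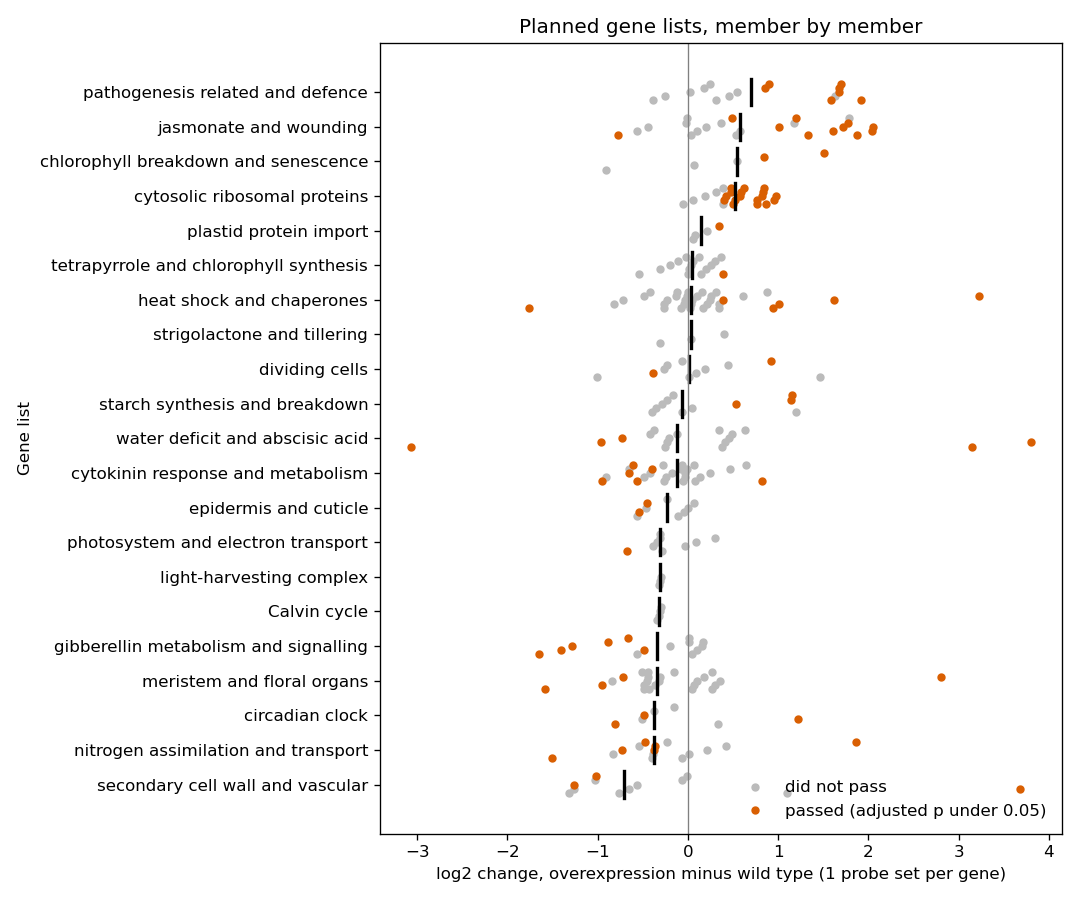
Log2 change (overexpression minus wild type) of every tested member of the planned gene lists other than the regulators, 1 point per gene, with list medians as black bars. Orange points passed an adjusted p of 0.05 and grey points did not. Cytosolic ribosomal protein genes sit mostly to the right of 0, with a median of 0.52.

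Camera called 7 of the 33 lists with at least 5 tested genes, 3 higher (ribosomal, jasmonate, defence) and 4 lower (gibberellin, photoreceptors, roots, aquaporins). None passed with an estimated correlation, where the smallest adjusted p was 0.415, so these calls hold only under the preset setting. A higher correlation alone cannot be the reason. The estimates for gibberellin (-0.047), roots (-0.084) and aquaporins (-0.008) lay below the preset 0.01, and those calls ended too. All 7 lists shared 0.415 whatever their estimate, from -0.084 to 0.548. That value therefore does not tell the lists apart and is no evidence against any single one. Why the calls ended was not tested. Among genes named above, PRR95 did not pass in 10, LTPL1 and MT2C in 9, and GLN2, ISPG and Cht2 in 8 of 15 alternatives. In fry, which asks whether a list's genes move without comparing them with other genes, 17 lists passed for 1 direction (7 up, 10 down) and 31 for change in either direction. Median and mean differed in sign for starch (-0.07 and 0.23, camera up), abscisic acid (-0.12 and 0.19, camera down), isoprenoids (-0.08 and 0.01, camera down), expansins (0.07 and -0.05, camera down), peroxide (-0.04 and 0.16, camera up), ethylene (-0.28 and 0.22, camera down and fry up) and phenylpropanoid genes (-0.11 and 0.17, camera up).

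Among the control probe sets, 6 pairs of 3' and 5' probe sets for rice transcripts had both ends at or above the filter on dim probe sets. The ratio was higher on every overexpression array in 2 of them, both of actin, and lower on every one in 0. The other of these actin pairs had ratios of 2.83 ± 0.40 in wild type and 4.76 ± 2.2 in overexpression (SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest possible). The remaining actin pair had an exact permutation p of 0.4, GAPDH 0.2, cyclophilin 0.8 and ubiquitin 0.6. The GAPDH ratio was 4.74 ± 0.47 in wild type and 4.02 ± 0.64 in overexpression (SD, n = 3 each). Among the 34 other pairs, the ratio was higher on every overexpression array in 5 and lower on every one in 3. These included bright spiked-in controls without leaf RNA, a higher CreX pair (means 1.1 in wild type and 1.16 in overexpression) and a lower bioD pair (1.81 and 1.57). Separation of the groups alone is therefore no measure of leaf RNA quality. Of 64 reporter probe sets, which carry sequences of vectors and marker genes, 1 was higher on every overexpression array, with an overexpression mean below that filter, and 8 were lower on every one. Another reporter probe set read 0.6 on wild type replicate 2 and between 226.4 and 250.1 on the other 5 arrays.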

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

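The rule for control probe sets was chosen after their values had been seen. In data outside the comparison of genes, 2 control probe sets read higher on every overexpression array than on any wild type array and had an overexpression mean of at least 16.8, the value of the filter on dim probe sets. The 3' probe set of GAPDH had a mean of 4672.2 in overexpression and 4315.9 in wild type. A probe set for a Bacillus subtilis thr control had means of 16.8 and 4.1. Each had an exact permutation p of 0.1, two-sided, the smallest that 3 arrays against 3 allow, and among 187 control probe sets 37 had non-overlapping groups, where chance gives 10%. Most of these went the other way: 4 were higher and 33 lower on every overexpression array, and of those with a mean over all arrays of at least 16.8, 1 was higher and 13 lower. The lower ones included 4 rice actin probe sets and all 3 bright ubiquitin probe sets (6820.3 in wild type and 5780.5 in overexpression, 8907.1 and 7423.6, 9198.2 and 7648.4). They also included probe sets of the spiked-in controls cre, bioB, bioC and bioD, which carry no leaf RNA. Among these were a cre probe set (8356 and 7124.7) and a bioB probe set (129.1 and 86.6). Over all 27 spiked-in probe sets, 19 had a negative log2 change.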

How the results depend on the processing

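The 4578 probe sets stayed within 1.5 times under most settings. They became 7945 with array weights (46.7% of them higher, against 53.8%), 1670 with at least a 2-fold change (65.6% higher) and 7250 at an adjusted p under 0.10 (47.4%). The weight of overexpression replicate 3 was 2.935, against 0.626 and 0.487 for replicates 1 and 2. Calls gained or lost with array weights therefore rest mostly on that array within overexpression. Leaving out 1 array gave between 2230 and 5533 (47.6% higher, without overexpression replicate 2), with 2408, 2287 and 2483 (60.9%, 63.1% and 64.1% higher) without wild type replicates 1, 2 and 3 and 2230 without overexpression replicate 3. The 7 gene lists became 4 with array weights and 0 with an estimated correlation, and between 4 and 7 with 1 array left out (4 without wild type replicate 2). The auxin list gained a call with the stricter filter (0.0457) and without overexpression replicate 1 (0.0319), where gibberellin lost its own. Under the stricter filter fewer genes were tested, 24 auxin and 9 gibberellin genes against 38 and 14. Without overexpression replicate 1 fewer arrays were fitted. Otherwise the cause was not tested. The replicate numbers did not pair the arrays. Correlations of deviations between same-numbered arrays were 0.097, -0.013 and -0.056, and with the replicate number as a block 3342 probe sets and 7 lists passed. The OsCGA1 result could not be run under any setting.

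Of 115 named genes that passed, 63 passed in every alternative and 52 lost the call in at least 1. Of the 20 with the largest changes, 12 passed in every alternative. ABA8OX1, CYP714C2 and NAS1 lost it in 1, EM in 2, URH2 in 4, PM1 in 6, and DREB1G and LEA19 in 8. Medians of lists that never passed changed sign. Under quantile normalization these were starch (0.087), sugars (-0.013), peroxide (0.173) and meiosis (0.06), and the gene LHCP (0.003). With array weights these were starch (0.025), dividing cells (-0.057), expansins (-0.043), peroxide (0.07) and phenylpropanoids (0.013), and with no filter expansins (-0.048) and sugars (-0.068). With 1 array left out, medians ran from -0.043 to 0.129 for chlorophyll synthesis, -0.266 to 0.113 for dividing cells, -0.169 to 0.105 for abscisic acid, -0.196 to 0.167 for expansins, -0.076 to 0.144 for sugars, -0.088 to 0.078 for peroxide, -0.23 to 0.199 for phenylpropanoids and -0.169 to 0.129 for meiosis. OEP21 ran from -0.035 to 0.113 and D3 from -0.068 to 0.091. For these the cause was not tested.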

Other observations

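The tests of other probe sets, linked segments, brightness-matched lists and spiked-in controls, with their limits, were chosen only after the result was seen. Only 10 splits of 6 arrays into groups of 3 exist, too few for a share under 0.05. The real split gave 4578 probe sets and the highest other split 0, so 1 split gave as many. For gene lists the real split gave 7 and the highest other split 8, and 2 of the 10 splits gave as many.

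A set of 51 probe sets changed at least 16-fold on the log2(signal + 3) scale, 37 higher and 14 lower, with OsPIP2;6 the named gene among them. A sequence difference between the plant lines under single probe sets would leave a gene's other probe sets in place, and the 14 other tested probe sets of 9 such genes had a median change of 3.02 in the same direction. That value decides nothing, since 5 of the 14 had met the 16-fold limit themselves and the other 9, which by that choice lie below it, had a median of 1.98 (from -0.44 to 3.92), so the explanation may hold for some of these genes. Linked segments from another genetic background could place such genes near each other, but 1 pair lay 5 to 20 tested genes apart, and 4240 of 10000 relabellings had as many. Their spread over 12 chromosomes was uneven (5 on chromosome 12 and none on chromosomes 3, 6, 9 and 10, permutation p = 0.0167). That spread was tested because it looked uneven and so decides nothing. With 23 such genes placed, background and overexpression cannot be told apart here.

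Ribosomal protein genes are bright, so a brightness-dependent difference between arrays was tested as a source of their rise. Their median change of 0.52 lay above the central 95% (-0.26 to 0.12) of 10000 random lists matched on mean signal, which argues against it. The correlation estimated between their members was 0.548, and their call ended with it (adjusted p = 0.415), as did those of lists with an estimate below the preset value. A biological origin in the genotype is a hypothesis that stays open.

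Photosynthesis genes gave the opposite result. The median change of 16 light-harvesting, photosystem and Calvin cycle genes was -0.31, within the central 95% (-0.36 to -0.21) of 10000 brightness-matched lists. A brightness-dependent difference may therefore account for the lower median of the set, but not for every member. LFNR1 was at -0.43 and passed under quantile normalization. That normalization also left PSAG nearly unchanged and FBPase only partly reduced, though neither passed there, while CAB2R, RCABP69 and rca moved close to no change. Bright leaf transcripts without a name could themselves serve photosynthesis. Bright spiked-in controls, which carry no leaf RNA, had a median change of -0.10 over 11 probe sets (10 lower), closer to 0 than -0.31, which leaves part of the difference open. All 11 detect bioD or cre, so they are not independent of each other.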
